A study of Mus musculus with 2 samples.

How the data were processed

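The series held 2 mouse RNA-seq libraries of sorted liver hepatocytes, 1 labelled as untreated and 1 as taken 24 h after 300 mg/kg acetaminophen. Libraries were made with a Tecan mRNA-seq kit, per the labels' protocols. Per the submitters' processing notes, HISAT2 and Subread were used with the mouse genome build mm39, and no versions were given. The annotation, the strand setting, the handling of read pairs and the number of animals per library were not given in the sources used here.

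The first of the deposited tables held raw counts per Ensembl gene, which the authors had not normalized: whole numbers with a different total in each library. Genes with 0 counts in both libraries were not in that table. The second of the deposited tables held a normalized signal, in which the authors divided each gene count by 1 size factor per library. The quotient of both tables was constant within each library to 8.9e-16, with size factors of 0.894 for control and 1.12 for APAP, equal to the DESeq2 median-of-ratios factors computed here from the counts. The tool the authors used for this step was not given in the sources used here. All results start from the raw counts, and the normalized signal served as an alternative scaling.

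Gene symbols were taken from a table that pairs Ensembl identifiers with symbols, which matched 20679 of the 20823 listed identifiers. The 144 genes without a symbol held 0.155% of counts in the control library and 0.185% in the APAP library and were kept in totals under their identifiers. No coordinates are given, because the annotation at hand was of another build than mm39.

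Library totals were 52419864 counts for control and 51009898 for APAP. They were scaled with the trimmed mean of M-values (TMM) of edgeR 4.0.16 in R 4.3.3, which gave factors of 0.887 and 1.13 and effective totals of 46508421 and 57493500. CPM values are counts scaled to an effective total of 1000000, so 1 count was worth 0.0215 CPM in the control library and 0.0174 CPM in the APAP library. The fold of a gene is the ratio of its CPM values, APAP over control, and its 95% interval is the exact conditional Poisson interval (Clopper-Pearson). Values described as n-fold lower are the inverse of that ratio. A gene with 0 counts in 1 library was given a bound against a floor of 3 counts in that library, which is 0.0645 CPM for control and 0.0522 CPM for APAP; this bound takes the count of the other library without error. Single levels carry exact Poisson intervals. Intervals and floors cover counting error only. Low counts were mostly even numbers: 68.3% of counts from 1 to 20 in the control library and 70.7% in the APAP library. If read mates were counted separately the intervals printed here are too narrow, so an alternative halved all counts for the interval. It kept the minimum of 20 on the unhalved counts and was not run for lists or named genes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for all other steps.

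With 1 library per group no test of the conditions was possible and none was made. A gene was counted as higher or lower if its fold was at least 2 in that direction, its interval excluded 1 and the 2 libraries together held at least 20 counts. Gene lists were described by the median log2 fold, with a prior of 0.5 counts, of members with at least 20 counts. The percentile of this median was taken among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was said to stand apart in the lowest or highest 2.5% of them. The design, the 48 gene lists, the alternatives and the rule for named genes were set before the data were examined, and 4 further lists and 3 further alternatives were chosen after seeing the data. Named genes were a fixed set of liver, injury and sort genes; the 12 genes in each direction with the interval bound farthest from 1, among those with at least 100 counts in the higher library and a symbol other than those of predicted, clone-named or mitochondrial genes; and, for each list, the 3 members farthest in each direction under the 2-fold rule and the 2 most abundant ones.

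The steps were tested on simulated data for this comparison with 20823 genes and counts drawn around the mean CPM of both libraries. Of genes made 3-fold and 6-fold higher, 50 of 50 and 50 of 50 were called, and of genes made 3-fold and 6-fold lower, 45 of 50 and 46 of 50. Of 20623 unchanged genes, 65 were called, but these included genes below the count minimum, which could not be called. The interval held the true fold for 13490 of 14096 genes (95.7%). Of 100 random lists of 25 genes, 4 were called with no shift, a share set by the list rule itself, and 100 after a shift of 1 in log2. With 1 library per group the spread between animals or libraries was unknown. These shares therefore check the steps on drawn counts and give no error rate for the real libraries.

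Alternatives were scaling by total counts, by DESeq2 1.42.0 size factors, by the authors' normalized signal and by totals without genes above 1% of a library; count minimums of 1 and 100; the deeper library thinned to the total of the shallower one; a 4-fold rule; and a rule that the whole interval lay beyond 2-fold. For lists they were random lists without matching, members of 1 list only and a prior of 5. Added after seeing the data were halved counts for the interval, a correction for transcript length and GC content in 10 by 10 bins, and totals without mitochondrial and Mup genes. Leaving out replicates was not possible with 1 library per group.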

Results

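Messenger RNA was sequenced from hepatocytes of C57BL6J mice aged 8 weeks, in 1 control library and 1 library made 24 h after an intraperitoneal dose of 300 mg/kg acetaminophen (APAP). APAP is a painkiller that cytochrome P450 enzymes, chiefly those of hepatocytes around the central vein, turn into a reactive product that depletes glutathione and kills these cells. After collagenase perfusion, flow cytometry removed cells carrying CD31, an endothelial protein, or CD45, a leukocyte protein. From the rest, 20000 hepatocytes with high surface Cxcr2, a receptor for neutrophil-attracting chemokines, were collected per library. The deposited table listed 20823 genes, with 52419864 counts in the control library and 51009898 in the APAP library. A count was recorded for 18058 genes in the control library and for 19358 in the APAP library.

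The comparison asks how the transcripts of these sorted hepatocytes differed between an untreated liver and a liver 24 h after APAP. As groups, acute phase, unfolded protein response and mitotic transcripts were higher in the APAP library, and the median transcript of the pericentral, drug metabolism and bile acid lists was lower. Lcn2, an iron-scavenging acute phase protein, was 573-fold higher (95% counting interval 420 to 802), from 0.860 to 492 CPM (counts scaled to a library total of 1000000). Cdkn1a, which encodes the cell cycle inhibitor p21, was 55.8-fold higher (43.7 to 72.2), and Mki67, a marker of cycling cells, was 15.8-fold higher (10.3 to 25.5). Cyp2e1, the main enzyme that activates APAP, was 8.92-fold lower (8.84 to 8.99), from 9626 to 1079 CPM. Glul, the glutamine synthetase of the hepatocytes next to the central vein, was 9.78-fold lower (9.18 to 10.4).

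Of the 14096 genes with at least 20 counts in the 2 libraries together, 1513 (10.7%) were at least 2-fold higher in the APAP library and 999 (7.09%) were at least 2-fold lower, each with a counting interval that excluded 1. The other 11584 genes met neither rule. There were 86 genes with at least 20 counts that were counted in the APAP library alone and 19 in the control library alone. With 1 library per group there was no replicate check and no p-value could be given, so intervals and counts of genes cover counting error only and compare these 2 libraries, not the conditions. Reads carried no molecular identifiers and were not independent molecules, and low counts were mostly even, so that intervals are too narrow if read mates were counted separately. Scaling by total counts moved every log2 fold by 0.35, and gave 2435 higher and 626 lower genes. Totals without the genes above 1% of a library moved every log2 fold by 0.34, and gave 2423 higher and 629 lower genes. The share of higher genes among those meeting the rule was 60.2% in the main scaling, 79.5% with total counts and 79.4% without the genes above 1%. The log2 fold of a gene that lay below 0 by less than these shifts therefore lay above 0 with both of these scalings.

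**Figure D1:**
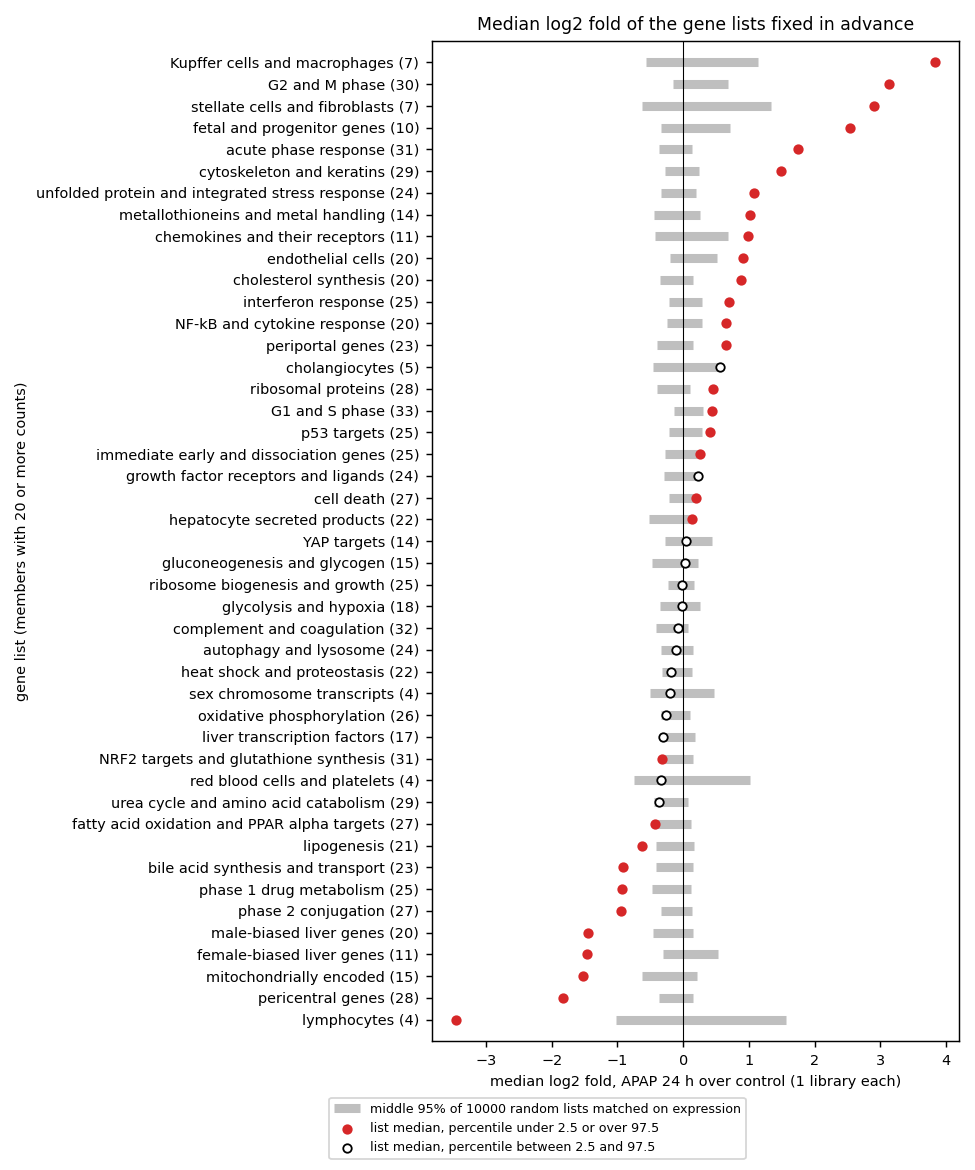
Each point is the median log2 fold (APAP 24 h over control, x axis) of a gene list fixed in advance, with 1 library per group, and the number in brackets is how many members had at least 20 counts. Grey bars span the middle 95% of 10000 random lists matched on expression; red points, such as G2 and M phase at 3.14 and pericentral genes at -1.83, lie outside this range, while 8 of the open points near 0, and NRF2 targets, change sign when libraries are scaled by total counts.

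The genes of the sort were examined first. Cxcr2 (ENSMUSG00000026180) had 0 counts in the control library and 2 in the APAP library, which is below the floor of 3 counts, so no fold was given. Its upper counting bounds were 0.0793 and 0.126 CPM, so the transcript was near absent from both libraries and a difference was not detectable. Transcript counts thus gave no sign of the high Cxcr2 of the sort, which was made on surface protein. Cxcr1 and Ptprc, which encodes CD45, were not listed. Pecam1, which encodes CD31, had 25 counts in the control library and 96 in the APAP library, 3.11-fold higher (1.98 to 5.04) but at only 1.67 CPM. The hepatocyte transcript Alb, which encodes albumin, took 2.59% of all counts in the control library and 5.17% in the APAP library.

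Among the genes with the largest folds upward were several with few or 0 counts in the control library. The metal-binding protein gene Mt2 had 2 counts in the control library and 1751 in the APAP library, a ratio of 708 (196 to 5853). The chemokine gene Cxcl14 had 0 and 503 counts, at least 136-fold higher. Against the same floor, Sprr1a, a cornified envelope protein gene, was at least 95.2-fold higher, Hid1 at least 81.7-fold, Nipal1 at least 74.7-fold and the lectin gene Lgals3 at least 59.3-fold higher. Their lower interval limits were 77.0, 66.0, 60.3 and 47.8. The basement membrane gene Nid1 was 95.9-fold higher (60.5 to 162), the transcription factor gene Bhlha15 was 82.0-fold higher (41.4 to 191), and Prtn3, a serine protease best known from neutrophil granules, was 74.3-fold higher (37.5 to 173). Apoa4, an apolipoprotein gene, was 59.3-fold higher (54.6 to 64.4) and reached 736 CPM.

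Among the genes with the largest folds downward, Slc1a2 (ENSMUSG00000005089), a glutamate transporter gene of pericentral hepatocytes, had 3165 counts in the control library and 0 in the APAP library, at least 1304-fold lower. Moxd1 was 354-fold lower (224 to 597), the lipoprotein lipase gene Lpl had 467 and 2 counts, a ratio of 0.00346 (0.000418 to 0.0126), and the carboxylesterase gene Ces2b had 183 and 2 counts, a ratio of 0.00884 (0.00106 to 0.0324). The carbonic anhydrase gene Car1 was 79.7-fold lower (30.8 to 295), the steroid dehydrogenase gene Hsd3b5 was 29.3-fold lower (26.8 to 32.0), and Ighm, the immunoglobulin mu heavy chain, was 57.1-fold lower (25.9 to 157). The major urinary protein genes Mup19, Mup17, Mup16, Mup15 and Mup2 also belonged to this group, and 20 of the 22 Mup genes were at least 2-fold lower. Near-identical copies of Mup genes share reads, so the value of any single copy is uncertain. The Mup genes together took 9.49% of counts in the control library and 1.56% in the APAP library.

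The medians of pericentral and of periportal genes differed between the libraries in opposite directions, which gives no position of any cell in the lobule. Of 28 pericentral genes, 20 were at least 2-fold lower in the APAP library and 0 were higher, with a median log2 fold of -1.83 at percentile 0 of 10000 random lists matched on expression. Cyp3a11 was 3.83-fold lower and Cyp1a2 was 2.52-fold lower. Oat, an ornithine aminotransferase gene, was 6.22-fold lower (6.04 to 6.41), Cyp2c37 was 9.57-fold lower (9.13 to 10.1), and Lgr5, a receptor gene that marks hepatocytes with strong WNT signalling, was 41.1-fold lower (25.8 to 69.8). Of 23 measured periportal genes, 7 were at least 2-fold higher and 0 were lower, with a median log2 fold of 0.65 at percentile 100. The list was not uniform: in the main scaling, counting intervals lay wholly above 1 for 15 members and wholly below 1 for 8. The serine dehydratase gene Sds was 15.1-fold higher (13.6 to 16.8) and Sdsl was 11.1-fold higher (8.66 to 14.3). Pck1 was 1.95-fold and Cyp2f2 1.12-fold higher, and Cps1, the first enzyme of the urea cycle, was 1.40-fold lower.

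**Figure D2:**
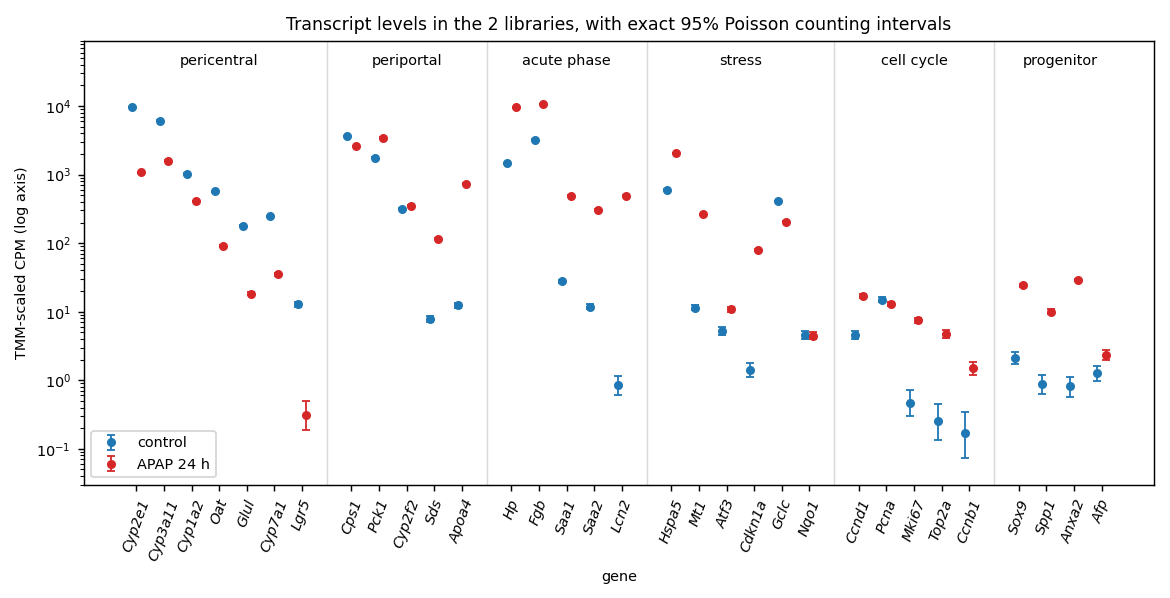
TMM-scaled CPM on a log axis for selected genes in the control library (blue) and the APAP library (red), with exact 95% Poisson intervals of counting error and 1 library per group. Cyp2e1 went from 9626 to 1079 CPM, Lcn2 from 0.860 to 492 CPM and Mki67 from 0.473 to 7.48 CPM, while Nqo1 was at 4.54 and 4.49 CPM.

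Both lists of drug-metabolising genes had medians below 0. Of 25 genes of phase 1 metabolism, 11 were at least 2-fold lower and 1 was higher, with a median log2 fold of -0.93 at percentile 0.01, or -0.55 at percentile 2.9 with members of no other list. The carboxylesterase gene Ces1d was 6.24-fold lower, whereas Cyp4a14, a fatty acid hydroxylase gene, was 32.3-fold higher (30.5 to 34.2). Of 27 genes of phase 2 conjugation, 12 were at least 2-fold lower and 2 were higher, with a median log2 fold of -0.95 at percentile 0. The glucuronosyltransferase genes Ugt2b1 and Ugt1a1, which conjugate drugs and bilirubin, were 9.66-fold lower (9.36 to 9.97) and 3.45-fold lower (3.26 to 3.66). The glutathione transferase gene Gsta3 was 3.30-fold lower, while Gsta1 was 10.2-fold higher (9.14 to 11.3) and the sulfotransferase gene Sult1a1 was 2.54-fold higher.

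Targets of NRF2, the transcription factor that answers oxidative stress, went both ways. Of 31 members, 5 were at least 2-fold higher and 6 were lower. The median log2 fold was -0.33 at percentile 2.47, but the mean was 0.15, and with totals by counts the median was 0.0176. The list lay among random lists at percentile 9.04 after the length and GC correction and 25.38 with members of no other list. The glutathione synthesis genes Gclc and Gclm were 2.02-fold and 1.26-fold lower, Gclm lying just above 1 with total counts, and Hmox1, which encodes haem oxygenase, was 1.60-fold lower (interval of the ratio 0.511 to 0.760). Nqo1 had a ratio of 0.989 (0.821 to 1.19), so no difference was detectable at this depth in the main scaling, and it lay above 1 with total counts. Txnrd1, the thioredoxin reductase gene, had a ratio of 0.822, which lay above 1 with total counts. The catalase gene Cat was 2.70-fold lower, whereas the transporter gene Abcc4 was 18.1-fold higher (8.60 to 45.9) and Cbr3 was 9.38-fold higher (4.92 to 20.1).

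Metallothioneins and metal-handling genes were higher as a group, with 7 of 14 at least 2-fold higher, 0 lower and a median log2 fold of 1.01 at percentile 100. Mt1 was 23.4-fold higher (21.5 to 25.6). Of 31 acute phase genes, 26 were at least 2-fold higher and 0 were lower, with a median log2 fold of 1.74 at percentile 100. The serum amyloid genes Saa1 and Saa2 were 17.7-fold higher (16.7 to 18.7) and 26.0-fold higher (23.9 to 28.4). Hp and Hpx, which encode the haemoglobin and haem carriers haptoglobin and hemopexin, were 6.50-fold and 6.20-fold higher. The fibrinogen genes Fga, Fgb and Fgg were 3.14-fold, 3.35-fold and 3.32-fold higher, and C3 was 2.66-fold higher.

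Other inflammatory lists were higher by smaller amounts. Macrophage, endothelial and stellate cell markers, from cells that also express such genes, were higher in the same library at median log2 folds of 2.69, 0.91 and 2.501 with genes at 0 counts at their bound, so the source of these transcripts stays open. Among 25 interferon response genes 9 were at least 2-fold higher and 0 lower (median log2 fold 0.69, percentile 100), with Stat2 at 2.51-fold and Mx2 at 2.74-fold higher. In the NF-kB and cytokine list 7 of 20 genes were at least 2-fold higher and 0 lower (median log2 fold 0.65, percentile 99.99), among them Tnfaip3, a feedback inhibitor of NF-kB, at 4.99-fold higher (3.38 to 7.60), and the interleukin-1 receptor gene Il1r1 at 2.99-fold higher. Of 11 measured chemokine and receptor genes 5 were at least 2-fold higher and 0 lower (median log2 fold 0.99, percentile 99.61), while 19 members of this list were not listed. Cxcl1, a ligand of Cxcr2, was 8.89-fold higher (7.49 to 10.6) and reached 27.1 CPM, and Cxcl12 was 1.26-fold higher.

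As a group, genes of the unfolded protein and integrated stress responses were higher, with 14 of 24 at least 2-fold higher, 0 lower, 10 that met neither rule and a median log2 fold of 1.08 at percentile 100. Hspa5, the main chaperone of the endoplasmic reticulum, was 3.42-fold higher (3.37 to 3.46), Sdf2l1 was 5.84-fold higher and Creld2 was 6.05-fold higher. Psat1, a serine synthesis gene induced by ATF4, had 6 and 407 counts and was 54.9-fold higher (24.99 to 150). Atf3 was 2.05-fold higher and Trib3 was 1.60-fold higher. Other genes of this list, chosen after their values were seen, stood on both sides of 1. Ddit3 was 3.23-fold higher (2.765 to 3.79) and Atf5 was 2.14-fold higher, whereas Asns had a ratio of 0.720 (0.603 to 0.859), Atf4 had a ratio of 1.24, and Chac1 and Ppp1r15a had ratios of 0.882 and 0.961, the last 2 lying above 1 with total counts. Heat shock and proteasome genes did not stand apart: 2 of 22, Hspa1a and Hspa1b, were at least 2-fold lower, 0 were higher, and the median log2 fold was -0.18 at percentile 23.2, or 0.16 with total counts.

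Of 30 genes of the G2 and M phases, 28 were at least 2-fold higher and 0 were lower, with a median log2 fold of 3.14 at percentile 100. The DNA topoisomerase gene Top2a was 18.4-fold higher (10.4 to 36.1), the cyclin gene Ccnb1 was 8.70-fold higher (4.22 to 20.8) and Aurka was 2.08-fold higher (1.67 to 2.60). The mitotic kinase genes Plk1 and Aurkb were at 0 counts in the control library and at least 42.3-fold and 20.5-fold higher against the floor of 3 counts. Their lower interval limits were 34.0 and 16.3. These transcripts stayed at low levels, with a median of 1.98 CPM in the APAP library and 0.258 CPM in the control library. Markers of other cells were also higher in that library, with median log2 folds, taking genes at 0 counts at their bound, of 2.69 for macrophages, 2.501 for stellate cells and fibroblasts and 0.91 for endothelial cells. Of 33 genes of the G1 and S phases, 6 were at least 2-fold higher and 1 was lower (median log2 fold 0.44, percentile 99.84). Ccnd1, the cyclin of G1 entry, was 3.73-fold higher (3.21 to 4.35) and the replication helicase gene Mcm6 was 3.39-fold higher. Pcna, the replication clamp, had a ratio of 0.868, which lay above 1 with total counts, and the transcription factor gene Myc was 12.8-fold lower (11.5 to 14.4).

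Targets of p53 included genes on both sides, with 7 of 25 at least 2-fold higher and 1 lower (median log2 fold 0.41, percentile 99.66). Beside Cdkn1a, the death receptor gene Tnfrsf10b was 9.20-fold higher (4.48 to 21.96) and Gdf15 was 1.53-fold higher. Mdm2, which encodes the main negative regulator of p53, had a ratio of 0.852 (0.795 to 0.913) that lay above 1 with total counts. In the cell death list 3 of 27 genes were at least 2-fold higher and 0 lower (median log2 fold 0.20, percentile 97.67, or 90.06 to 97.1 under 5 alternatives that put it among random lists), with the necroptosis effector gene Mlkl at 2.33-fold and the TWEAK receptor gene Tnfrsf12a at 4.01-fold higher. Immediate early genes, which tissue dissociation also induces, had 6 of 25 members at least 2-fold higher and 5 lower (median log2 fold 0.26, percentile 98.68), but lay among random lists at percentile 96.98 after the length and GC correction and 94.42 without matching. Klf6 was 5.93-fold higher and Nr4a1 was 2.92-fold lower.

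Fetal and progenitor genes had 6 of 10 measured members at least 2-fold higher and 3 lower, with a median log2 fold of 2.54 at percentile 100 and a mean of 1.07. The 3 lower members were Lgr5, 41.1-fold lower, Scd2, 7.48-fold lower, and Krt23, with 34 and 0 counts. Sox9, a transcription factor gene of biliary and progenitor cells, was 11.4-fold higher (9.31 to 14.2), and the osteopontin gene Spp1 was 11.3-fold higher (8.23 to 15.9). The annexin gene Anxa2 was 35.6-fold higher (25.8 to 50.4), while Afp, the fetal albumin homologue, was 1.84-fold higher (1.34 to 2.54) and remained at 2.33 CPM. Cytoskeletal genes had 18 of 29 members at least 2-fold higher and 1 lower (median log2 fold 1.48, percentile 100), with the keratin gene Krt8 at 3.54-fold and the calcium-binding protein gene S100a11 at 28.3-fold higher. The endothelial, macrophage and stellate cell lists were higher in the same library, at percentiles 99.99, 100 and 99.98. The cholangiocyte list, which shares Sox9 and Spp1, stood at percentile 96.8, or at 100 with a minimum of 1 count. Targets of the growth regulator YAP did not stand apart, with 4 of 14 at least 2-fold higher and 2 lower (median log2 fold 0.04, percentile 45.8), but stood apart at 0.68 and percentile 99.25 with a minimum of 1 count. Ccn2 had 1 and 75 counts, a ratio of 60.7 (10.6 to 2428), whereas Ccn1 was 2.11-fold lower. Growth factor ligands and receptors had 6 of 24 members at least 2-fold higher and 1 lower (median log2 fold 0.23, percentile 97.1), but stood apart at 0.40 and percentile 99.55 with a minimum of 1 count, at 0.33 and 99.45 after the length and GC correction, and at 0.22 and 97.8 with a minimum of 100 counts. Osmr, the oncostatin M receptor gene, had 2 and 146 counts, a ratio of 59.1 (16.1 to 492), Fst, an activin antagonist gene, was 23.5-fold higher (13.9 to 43.4), and the growth hormone receptor gene Ghr was 2.43-fold lower.

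The lists of bile acid, fatty acid oxidation and lipogenic genes had medians below 0, and that of cholesterol synthesis had a median above 0. Of 23 genes of bile acid synthesis and transport, 11 were at least 2-fold lower and 1 was higher, with a median log2 fold of -0.92 at percentile 0. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 7.02-fold lower (6.70 to 7.37), Cyp8b1 was 2.68-fold lower, and the bile acid carriers Abcb11 and Slc10a1 were 2.37-fold and 2.14-fold lower. Of 27 genes of fatty acid oxidation and targets of the transcription factor PPAR alpha, 8 were at least 2-fold lower and 1 was higher (median log2 fold -0.43, percentile 1.30). The higher member was Cyp4a14, also in the phase 1 list, at 32.3-fold. The peroxisomal thiolase gene Acaa1b was 8.36-fold lower. Of 21 lipogenic genes, 6 were at least 2-fold lower and 0 higher (median log2 fold -0.62, percentile 0.03), with the desaturase gene Scd1 at 7.12-fold lower (7.06 to 7.18) and the fatty acid synthase gene Fasn at 2.01-fold lower. Of 20 genes of cholesterol synthesis, 8 were at least 2-fold higher and 0 lower (median log2 fold 0.88, percentile 100), with Lss at 3.56-fold, Mvd at 3.09-fold and Sqle at 2.91-fold higher.

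Secreted and metabolic genes of mature hepatocytes differed less as groups. Among 22 secreted products 5 were at least 2-fold higher and 0 lower, with a median log2 fold of 0.14 at percentile 97.98. It was -0.0199 at percentile 85.08 with members of no other list, and lay among random lists under 3 other alternatives. Alb was 1.57-fold higher, Apoa1 was 1.59-fold higher and the transferrin gene Trf was 2.39-fold higher. Among 17 liver transcription factors 3 were at least 2-fold lower and 0 higher (median log2 fold -0.31, or 0.04 with total counts, percentile 5.19, or 1.48 without matching). Hnf4a had a ratio of 0.949 (0.936 to 0.963) that lay above 1 with total counts, Cebpa was 1.82-fold lower and Onecut1 was 3.71-fold lower. The urea cycle and amino acid list had 2 of 29 genes at least 2-fold higher and 5 lower (median log2 fold -0.37, percentile 7.11, or 0.07 without matching). The lists of gluconeogenesis (0.03, percentile 83.5), glycolysis (-0.02, percentile 62.4), complement and coagulation (-0.08, percentile 77.1), ribosome biogenesis (-0.01, percentile 61.3) and autophagy (-0.11, percentile 48.5) had median log2 folds near 0, the negative ones lying above 0 with total counts. Pck1, the enzyme gene that commits carbon to glucose synthesis, was 1.95-fold higher. Ribosomal protein genes had a median log2 fold of 0.45 at percentile 100, although 0 of 28 were 2-fold higher or lower.

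Mitochondrially encoded transcripts were lower throughout, with 15 of 15 listed members at least 2-fold lower and a median log2 fold of -1.52 at percentile 0. The cytochrome oxidase transcript mt-Co1 was 3.63-fold lower. The mitochondrial share of all counts was 18.1% in the control library and 7.60% in the APAP library. Nuclear genes of oxidative phosphorylation had a median log2 fold of -0.26 at percentile 11.8 (1.2 without matching), or 0.08 with total counts, with 0 of 26 at least 2-fold lower or higher.

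Both lists of sex-biased liver genes had lower medians, but not every member was lower. Of 20 male-biased genes, 13 were at least 2-fold lower and 0 higher (median log2 fold -1.45, percentile 0), and of 11 female-biased genes, 7 were at least 2-fold lower and 2 higher (median log2 fold -1.46, percentile 0). The female-biased genes Cyp2a4 and Cyp3a16 were 5.46-fold and 5.73-fold lower, and Abcd2 was 9.66-fold higher (7.73 to 12.2). Y-linked transcripts were present in both libraries, with Ddx3y at 64.9 and 38.6 CPM and Eif2s3y at 31.2 and 30.1 CPM. The list of sex chromosome transcripts had a median log2 fold of -0.20 over 4 genes at percentile 23.7, or 0.15 with total counts.

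Markers of other liver cells were mostly low but not equal between the libraries. Exceptions in the control and APAP libraries were the macrophage markers Slc40a1, also in the metal-handling list (74.95 and 67.8 CPM), and Mpeg1 (23.2 and 53.1 CPM). The cholangiocyte marker Anxa4 was at 34.8 and 51.1 CPM. Of 20 endothelial markers, 8 were at least 2-fold higher in the APAP library and 2 lower (median log2 fold 0.91, percentile 99.99), with Cdh5 at 6.50-fold higher (4.28 to 10.3) and Stab2 at 2.09-fold lower. Their median level was 1.46 CPM in the control library and 2.41 CPM in the APAP library. Of 7 measured macrophage markers 5 were at least 2-fold higher and 0 lower, with a median log2 fold of 3.84 at percentile 100. The median was 2.69 with genes at 0 counts set at their bound, for which no percentile was taken. With a minimum of 100 counts the macrophage median was 0.69 at percentile 93.1. Cd68, a lysosomal protein gene of macrophages, had 3 and 287 counts, a ratio of 77.4 (26.2 to 378), and Mpeg1 was 2.29-fold higher. Cd14, 15.8-fold higher with 4 and 78 counts, also stands in the acute phase list. Of 7 measured stellate cell and fibroblast markers 6 were at least 2-fold higher and 0 lower, with a median log2 fold of 2.90 at percentile 99.98. The median was 2.501 with genes at 0 counts set at their bound, again without a percentile. Reln was 12.5-fold higher (8.86 to 18.1), but the collagen gene Col3a1 had only 0 and 21 counts. Cholangiocyte markers had 2 of 5 members higher and 0 lower (median log2 fold 0.55, percentile 96.8), and these 2 were Sox9 and Spp1. The list stood apart at 3.04 and percentile 100 with a minimum of 1 count, and at percentile 98.34 after the length and GC correction and 97.66 with a minimum of 100 counts.

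Blood cell markers were few, and many were not listed. The 4 measured lymphocyte markers had a median log2 fold of -3.46 at percentile 0, with 3 at least 2-fold lower, including Cd4 at 27.5-fold lower (10.4 to 103), which had 89 and 4 counts. Both measured pan-leukocyte markers, Lcp1 and Hcls1, were at least 2-fold lower. Of the 2 measured neutrophil markers, Lcn2 is also an acute phase gene, and Wfdc21 had a ratio of 0.988 (0.961 to 1.01), above 1 with total counts. Of 4 red blood cell and platelet markers 1 was lower, the haem synthesis gene Alas2 at 2.63-fold (median log2 fold of the list -0.34, percentile 12.8). The single measured mesothelial marker, Igfbp5, was 6.40-fold lower with 88 and 17 counts.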

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

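Halved counts, the length and GC correction, totals without mitochondrial and Mup genes and the 4 lists on clock, WNT and growth hormone genes were chosen after seeing the data; the other alternatives were fixed before. Against 1513 higher and 999 lower genes, scaling by total counts gave 2435 and 626, and totals without genes above 1% of a library gave 2423 and 629; all 1513 higher genes were among the higher ones in both cases, and the shift comes from the construction of the scaling. Fewer genes also met the stricter rules by construction: 817 and 634 with a minimum of 100 counts, 591 and 353 under a 4-fold rule, and 827 and 613 with the whole interval beyond 2-fold. The remaining alternatives kept the counts within 1.5 times, from 1269 to 1997 higher and from 882 to 1310 lower, with 1269 and 882 for halved counts. The authors' normalized signal and DESeq2 factors each gave 1489 and 1026.

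Of 31 lists that stood apart, 25 did so under each alternative that was run. Each alternative scaling moved the folds of list members and of random lists by nearly the same amount. By construction it could hardly change a percentile, so the 25 lists were checked by the other alternatives alone. Scaling moved the medians, and some that lay near 0 changed sign. NRF2 targets had a median log2 fold of 0.0176 with total counts and 0.0137 without genes above 1%. Percentile 2.69 in both cases put them among random lists. With total counts, 8 lists that did not stand apart changed sign. Secreted products had a median of -0.0199 with members of 1 list only, where all members shared with another list, such as Alb and the fibrinogen genes, are left out. NRF2 targets, phase 1 metabolism, immediate early genes, cell death and macrophage markers also fell inside the middle 95% of random lists under at least 1 alternative, macrophage markers with a minimum of 100 counts, and the cause was not tested. Of the 14 other lists, 6 stood apart under at least 1 alternative: YAP targets, cholangiocyte markers, growth factors, liver transcription factors, oxidative phosphorylation and the urea cycle. With total counts and without genes above 1%, log2 folds above 0 were found for Hnf4a (0.2697 and 0.2658), Clock (0.2452 and 0.2413), Mdm2 (0.1142 and 0.1104) and Txnrd1 (0.0629 and 0.0591). Clock also had 0.0907 after the length and GC correction, and the cause was not tested. No paired analysis was possible because each group had 1 library. No fold could be judged for transcripts near the floor of 3 counts, among them Cxcr2, which was near absent from both libraries.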

Other observations

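The tests and the 4 gene lists in this part were chosen after the results were seen. Core clock genes stood on both sides of 1. Of 11 genes that cycle in phase with Dbp, a transcription factor gene with strong daily rhythm, 6 were at least 2-fold lower in the APAP library and 0 higher (median log2 fold -1.20). Dbp itself was 15.5-fold lower (13.3 to 18.2), Usp2 was 4.16-fold lower and Tef was 2.29-fold lower. Of 5 genes in antiphase to Dbp, 4 were at least 2-fold higher and 0 lower (median log2 fold 1.41). Arntl, which encodes BMAL1, was 4.24-fold higher (3.61 to 4.995), Npas2 was 4.71-fold higher (3.24 to 7.03), Nfil3 was 2.65-fold higher, and Clock had a ratio of 0.933 that lay above 1 with total counts.

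Targets of growth hormone and of WNT were listed because some of their members, such as Hsd3b5, Moxd1, Lgr5 and Slc1a2, had been seen to be lower, so these lists describe that observation and do not test it. Of 13 targets of growth hormone and its mediator STAT5, 8 were at least 2-fold lower and 0 higher (median log2 fold -1.42). Socs2, a feedback inhibitor of growth hormone signalling, was 11.8-fold lower, while Igf1 was 1.18-fold higher. Of 12 WNT targets of hepatocytes near the central vein, 10 were at least 2-fold lower and 0 higher (median log2 fold -1.96), and 5 of the 12 were not members of the pericentral list.

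The lower pericentral median and the higher periportal median may have sources other than a change of transcript levels within cells. Transcript length and GC content were argued against as the whole source: after their trend was removed, the periportal median exceeded the pericentral median by 2.297 in log2, against 2.48 before. A larger share of periportal cells, or a smaller share of pericentral cells, among those sorted stays open. The folds spread by a quartile ratio of 3.649 for periportal and 3.271 for pericentral genes, and no table gives the zonal profile of each gene, so shares of cells cannot be told apart from transcript levels per cell. An effect of APAP, which the design names, also stays open as untested. It is not set apart from a smaller share of pericentral cells, since APAP kills such cells.

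Higher G2 and M phase transcripts could come from other cells, and no value excluded this. Leukocytes, which the CD45 gate was set to remove, stay open. The median upper counting bound of 37 listed markers (4 in another list, 8 at 1 CPM or more in the control library) was 0.1145 of the mitotic median in the APAP library. There Lyz2 and C1qa, chosen after their values were seen, had 4 counts each. Genes with 0 counts in both libraries were not listed, and 11 macrophage, 16 neutrophil, 18 lymphocyte and 12 pan-leukocyte markers were not listed. On the other side, Mpeg1 was at 53.1 CPM and Prtn3, which is in no marker list, at 12.8 CPM. Lcn2 was at 492 CPM but is also an acute phase gene, and Wfdc21, at 203 CPM, had a ratio of 0.988. Lcp1 was at 42.8 CPM though 2.42-fold lower. The macrophage median log2 fold was 2.69 with genes at 0 counts at their bound, or 0.69 with a minimum of 100 counts, and Cd68 was at 4.99 CPM, above the mitotic median of 1.98 CPM. Stellate cells, which neither the CD31 nor the CD45 gate was set to remove, stay open too, though the cells collected were those with high surface Cxcr2. The median upper counting bound of 21 listed stellate markers was 0.1613 of the mitotic median. Of these markers, 1 stands in another list and 1 reached 1 CPM in the control library. The 7 stellate markers with at least 20 counts, however, had a median log2 fold of 2.90, or 2.501 with genes at 0 counts at their bound. Reln was at 9.39 CPM. Endothelial markers were 1.876-fold higher at the median against 8.80-fold for the mitotic genes, but dividing endothelial cells, which the CD31 gate was set to remove, cannot be told apart from dividing hepatocytes, a response to APAP that the design leaves untested.

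For the clock genes, a different time of day at collection may be a source, as a hypothesis that these data do not decide: the antiphase median exceeded the in-phase median by 2.602 in log2, which restates the pattern and cannot be told apart from an effect of APAP on the clock. The labels give a time after APAP but no time of day for either library, and an effect of lower food intake was not tested.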
